A study of Homo sapiens with 16 samples.

How the data were processed

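The authors deposited a table of raw counts per gene for all 16 libraries. The submitters' processing notes name TopHat2 2.1.0, SAMtools 1.3, HTSeq and DESeq2 and the genome build hg19, and give no further settings. Per the labels' protocols, cells were transfected with Interferin reagent after seeding, RNA was extracted with a Nucleospin miRNA kit, polyadenylated RNA was captured, and libraries were made with a SureSelect Strand-specific kit. The strand setting of the counting was not stated, so antisense genes are called uncertain. For each of the 4 comparisons the authors also deposited a DESeq2 table with log2 fold changes of siZNF414 over siLuc, their standard errors, Wald scores, p-values and adjusted p-values. These log2 values, scores and p-values were used as deposited, only to set the authors' calls beside those made here. The mean level in those tables was not used.

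The deposited count table holds 60492 gene IDs and 5 summary rows. The summary rows were left out of all tests. As a percent of all counts they were 11.9 to 24.9% without a feature, 3.40 to 4.27% ambiguous and 17.3 to 21.9% not uniquely aligned. Symbols and hg19 coordinates came from the authors' tables for 18293 IDs and from a reference table for 37709, and 4490 IDs kept their ID only. Replicates of a group were not copies of each other: in all 8 pairs, counts differed with a chi-square per degree of freedom of at least 7.28.

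Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and the quasi-likelihood F test. Each line was fitted with its 8 libraries, 1 coefficient per group, and siZNF414 was set against siLuc at each time. Differences between times came from the same fits, and differences between lines from a fit of all 16 libraries. Genes past the threshold have a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. The quasi-likelihood test is 2-sided. Folds are given as log2 with their standard error (SE), and levels as counts per 1000000 (CPM) with the SD of the 2 libraries.

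For each comparison the 8 largest rises and the 8 largest falls were named, among genes past the threshold with a symbol, a mean of at least 5 CPM, and both siZNF414 libraries on the same side of both siLuc libraries. Where no gene passed, the 5 with the smallest p were named. Genes called at both times were ranked by the larger of their adjusted p, and up to 10 were named. Up to 4 genes were named for each test of a difference. Of each list, up to 4 members past the threshold with the smallest adjusted p could be named.

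The 34 gene lists, the comparisons and the alternatives were chosen before the data were examined. The lists held 948 genes, of which 941 were found in the count table. Lists of at least 5 tested genes were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01. Each was tested again with a correlation estimated from the data, and with fry. Camera asks whether a list's genes lie higher or lower than the other genes. The adjusted p of a list is over the lists of its comparison.

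Alternatives were RLE normalization, DESeq2 1.42.0, no filter on low counts, a stricter filter (a mean of 5 CPM, and 1 CPM in each library of at least 1 group), a replicate block, each library left out in turn, the 4 libraries of a comparison alone, all 16 libraries in 1 fit, and a test against a fold of 1.2. Added later were MCF-7 fits lacking siZNF414 12 h replicate 2, lists in fits of 4 libraries, a crossed block, and the naming rule applied to the MCF-7 24 h fit of 4 libraries. When a library is left out of a pair, the lone library is assumed to vary like the other groups.

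A self-test multiplied the expected counts of 200 genes by folds of 1.5, 2 or 4 in simulated counts with the dispersions of the data. At a fold of 2, edgeR recovered 65.7% of changed genes in Hs700T at 12 h, 70.1% at 24 h, 0% in MCF-7 at 12 h, 2.99% at 24 h and 70.1% in the MCF-7 24 h fit of 4 libraries. Unchanged genes made up 3.23 to 9.09% of the calls. Camera found a planted list of 40 genes shifted by 0.4 log2 in all 5 fits, and called 1 null list in MCF-7 at 24 h and none elsewhere. The simulated genes varied independently and the null lists were random. So this does not show how often camera errs on lists whose genes vary together, such as mitosis genes (estimated correlation 0.71 in Hs700T at 12 h).

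For 3' UTR sequences, GENCODE 29 basic transcripts on GRCh38 gave 19565 genes. All 16384 7-mers were considered, with fits adjusted for the length and GC content of the UTR. In its self-test each of 10 planted 7-mers came first, and the largest absolute t in shuffled data lay between 3.85 and 4.59. Other steps used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.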

Results

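RNA sequencing counted polyadenylated transcripts in Hs700T, a pancreatic cancer cell line, and MCF-7, an oestrogen receptor-positive breast cancer cell line. Each line was transfected with 10 nM of an siRNA against ZNF414, a zinc finger protein gene, or of a control siRNA against firefly luciferase (siLuc), and RNA was collected after 12 h or 24 h. The 8 groups of line, siRNA and time held 2 libraries each, 16 in all. Counts assigned to genes, in units of 1000000 (M) and for replicates 1 and 2 in order, were 57.5 and 79.7 M in Hs700T siLuc at 12 h, 40.5 and 61.8 M in Hs700T siZNF414 at 12 h, 123 and 122 M in Hs700T siLuc at 24 h, and 37.3 and 120 M in Hs700T siZNF414 at 24 h. In MCF-7 they were 67.2 and 88.5 M in siLuc at 12 h, 148 and 31.9 M in siZNF414 at 12 h, 57.4 and 112 M in siLuc at 24 h, and 87.7 and 142 M in siZNF414 at 24 h. Some markers separated the lines: in siLuc libraries at 24 h, GATA3, a luminal breast transcription factor, averaged 1127 counts per 1000000 (CPM) in MCF-7 and 23.2 CPM in Hs700T, whereas MSLN (mesothelin) averaged 181 CPM in Hs700T and 0.0841 CPM in MCF-7. Not all pancreatic duct markers did so, since KRT19, also a luminal marker, averaged 8.50 CPM in Hs700T and 1491 CPM in MCF-7, and MUC5AC 0.0317 and 29.2 CPM. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these libraries.

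The targeted gene was measured first, to check the labels. ZNF414 (ENSG00000133250.13_2) lies on the minus strand of chromosome 19 from 8574562 to 8579048 in hg19. In Hs700T at 12 h it stood at 11.7 and 8.70 CPM in the siLuc libraries and at 3.06 and 3.35 CPM in the siZNF414 libraries, a log2 fold change of -1.66 (SE 0.16, edgeR adjusted p = 2.65e-05). In Hs700T at 24 h it stood at 11.2 and 10.5 CPM against 2.68 and 2.68 CPM, a log2 fold change of -2.01 (SE 0.15, adjusted p = 6.50e-07). In MCF-7 at 12 h the values were 11.3 and 9.15 CPM against 2.71 and 5.75 CPM, and the log2 fold change of -1.295 (SE 0.37, adjusted p = 0.489) did not pass the test. In MCF-7 at 24 h they were 12.6 and 9.73 CPM against 3.14 and 3.57 CPM, and the log2 fold change of -1.74 (SE 0.37, adjusted p = 0.216) did not pass either. ZNF414 was lower in every siZNF414 library than in both siLuc libraries of its line and time. Without replicate 2 of the MCF-7 siZNF414 12 h group, the log2 fold change at 12 h was -1.93 and past the threshold, and without replicate 1 it was -0.85 and not past it. With only the 4 MCF-7 libraries of 24 h in the fit, the log2 fold change there was -1.73 (SE 0.16) and past the threshold. In the authors' deposited tables, ZNF414 had log2 fold changes of -1.64 and -1.96 in Hs700T at 12 h and 24 h and of -1.31 and -1.71 in MCF-7.

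**Figure D1:**
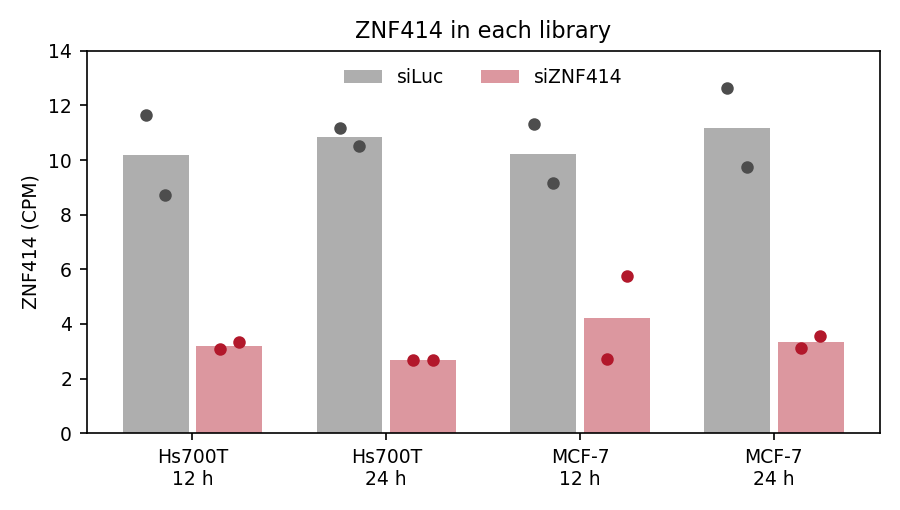
ZNF414 in counts per 1000000 (CPM) in each of the 16 libraries, by cell line and time. Bars give the mean of the 2 libraries of a group and points the single libraries; every siZNF414 library lies below both siLuc libraries of its line and time, and MCF-7 siZNF414 at 12 h has the widest pair (2.71 and 5.75 CPM).

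The comparison of siZNF414 with siLuc in Hs700T at 12 h asked which transcripts had changed first. UBE2V2, which encodes a variant ubiquitin-conjugating enzyme, rose from 89.6 ± 0.443 to 237 ± 13.6 CPM (mean ± SD, n = 2 per group; log2 fold change 1.40, SE 0.07). ITGB8, an integrin subunit that activates latent TGF-beta, rose from 22.4 ± 1.74 to 56.0 ± 0.212 CPM (1.32, SE 0.08), and PDCD4, an inhibitor of translation initiation, from 69.4 ± 2.42 to 155 ± 0.0306 CPM (1.15, SE 0.06). PLEKHA1 (1.18), LBR, the lamin B receptor (1.18), STC1, a secreted glycoprotein (1.12), TMX1, a thioredoxin-related transmembrane protein (1.10), and ENPP4 (1.05) completed the 8 largest rises. After ZNF414, the largest falls were NCEH1, a cholesteryl ester hydrolase (-0.88, SE 0.08), ISOC1 (-0.88, SE 0.08), the secretory carrier membrane protein SCAMP2 (-0.84, SE 0.08), LHFPL2 (-0.78), the mitochondrial elongation factor GFM2 (-0.75), the mitochondrial isocitrate dehydrogenase IDH2 (-0.71, SE 0.06) and the pseudogene PBX2P1 (-0.70). PBX2P1 is uncertain, since its reads could come from PBX2, and it was not past the threshold without siLuc replicate 1 (-0.61) or siZNF414 replicate 2 (-0.64). In hg19, UBE2V2 lies on chromosome 8 from 48920960 to 48977268, ITGB8 on chromosome 7 from 20370325 to 20455377, PDCD4 on chromosome 10 from 112631553 to 112659764 and IDH2 on chromosome 15 from 90626277 to 90645736.

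Among the gene lists at 12 h in Hs700T, 9 of the 32 tested passed camera. The immediate early and SRF targets had a median log2 fold of 0.25 (adjusted p = 4.94e-14), with 3 of 28 genes higher, none lower and 25 not past the test, and 13 higher when adjusted over the list alone. Their examples included the zinc finger factors KLF2 (0.88, SE 0.17) and KLF6 (0.32, SE 0.07). The list's call was lost with an estimated correlation (adjusted p = 0.748 with an estimated correlation). Of the p53 targets, 3 of 24 were higher, 0 lower and 21 not past the test (adjusted over the list alone, 3 and 0), among them MDM2, the ubiquitin ligase of p53 (0.61, SE 0.07), and RRM2B, a ribonucleotide reductase subunit (0.95, SE 0.13). The p53 list had a median of 0.06 and a camera adjusted p = 0.00214 (adjusted p = 0.458 with an estimated correlation). Of the apoptosis regulators, 4 of 25 were higher, 0 lower and 21 not past (adjusted over the list alone, 4 and 0). Its median log2 fold was 0.05 (adjusted p = 0.0131, and adjusted p = 0.748 with an estimated correlation). The epithelial state list had 2 of 24 higher, CDH1, the epithelial cadherin (0.31), and ELF3 (0.44), 0 lower and 22 not past (adjusted over the list alone, 2 and 0). The median of the list was 0.07 (adjusted p = 0.00259, and adjusted p = 0.884 with an estimated correlation). TGF-beta targets had 2 of 24 higher, among them the receptor TGFBR1 (0.51), 0 lower and 22 not past (adjusted over the list alone, 3 and 0). The list had a median of 0.09 (adjusted p = 0.00507, and adjusted p = 0.949 with an estimated correlation). The list of actin cytoskeleton and focal adhesion genes had 2 of 54 higher, among them the integrin ITGA6 (0.97, SE 0.06), 0 lower and 52 not past (adjusted over the list alone, 2 and 0). Its median log2 fold was 0.05 (adjusted p = 0.00275, and adjusted p = 0.949 with an estimated correlation). Without siLuc replicate 2, KLF2 (0.55), KLF6 (0.29), CDH1 (0.27), ELF3 (0.33) and TGFBR1 (0.47) were not past the threshold. Without siZNF414 replicate 1, KLF2 (0.97), KLF6 (0.37), CDH1 (0.28), ELF3 (0.42) and TGFBR1 (0.33) were not past it. KLF6 also lost its call without siLuc replicate 1 (0.34) or siZNF414 replicate 2 (0.26), and KLF2 (0.77) and ELF3 (0.46) without the latter. The calls of the lists of actin (median 0.01), TGF-beta (-0.01), epithelial (0.01) and apoptosis genes (-0.01) were lost without siLuc replicate 2, and those of actin (0.02) and TGF-beta genes (0.04) also without siZNF414 replicate 1. The medians of the immediate early and p53 lists were 0.08 and 0.01 without siLuc replicate 2, and 0.42 and 0.13 without siLuc replicate 1. Without siLuc replicate 1 those of actin, TGF-beta, epithelial and apoptosis genes were 0.09, 0.16, 0.12 and 0.10. Those of p53 and TGF-beta genes were 0.09 and 0.14 without siZNF414 replicate 2, and that of apoptosis genes was 0.08 without siZNF414 replicate 1.

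Most genes of the cell cycle lists did not pass the test at 12 h in Hs700T. The G1/S and DNA replication list had a median of -0.08 (adjusted p = 0.00214), with 1 of 41 genes lower, 2 higher and 38 not past the test (adjusted over the list alone, 4 lower and 2 higher; adjusted p = 0.882 with an estimated correlation). The mitosis and G2/M list had a median of 0.05 (adjusted p = 0.00761), with 1 of 40 genes higher, the kinetochore protein gene CENPF (0.58, SE 0.06), 0 lower and 39 not past (adjusted over the list alone, 1 and 0; adjusted p = 0.949 with an estimated correlation). The mitochondrially encoded transcripts had a median of -0.13 with all 13 not past the test (adjusted over the list alone, 0; adjusted p = 0.00214, and adjusted p = 0.949 with an estimated correlation). The G1/S call was lost without siLuc replicate 1 (median -0.07) or siZNF414 replicate 2 (-0.08), as was the mitosis call (-0.01 and 0.03), and the mitochondrial call was lost without siLuc replicate 2 (-0.06) or siZNF414 replicate 1 (-0.10). Without siLuc replicate 2 the G1/S and mitosis medians were -0.15 and 0.10, and without siLuc replicate 1 the mitochondrial median was -0.21. The other 23 lists had camera adjusted p from 0.0587 to 0.949. The test fry, which asks whether a list's genes moved on balance one way and compares it with no other genes, passed 0 lists at 12 h in Hs700T.

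By edgeR's quasi-likelihood test, 407 of 21521 genes passed in Hs700T at 12 h, 287 higher and 120 lower. The count was 188 without siLuc replicate 2, 167 without siZNF414 replicate 1 and 230 without siZNF414 replicate 2. It was 618 without a filter on low counts, 548 by DESeq2, 93 when tested against a fold of 1.2 and 10 with all 16 libraries in the fit. Of the 16 genes above only UBE2V2, PDCD4, LBR, PLEKHA1, TMX1, SCAMP2 and ISOC1 were past the threshold under every alternative run. The authors' deposited table held 112 genes at an adjusted p under 0.05, 78 higher and 34 lower, of which 107 also passed here, all in the same direction.

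The same contrast at 24 h in Hs700T asked which changes were present 12 h later. ITGB8 rose from 8.86 ± 0.192 to 46.6 ± 0.573 CPM (n = 2 per group; log2 fold change 2.39, SE 0.08), UBE2V2 from 69.6 ± 5.35 to 226 ± 5.11 CPM (1.70, SE 0.07) and LIPA, the lysosomal acid lipase gene, from 24.1 ± 0.146 to 72.7 ± 0.0833 CPM (1.59, SE 0.07). C15orf52 (1.68), STC1 (1.53) and PDCD4 (1.49) were also among the 8 largest rises. So were the antisense genes IGFL2-AS1 (2.12, SE 0.17) and PDK1-AS1 (1.498, SE 0.11), which are uncertain because the strand setting of the counting is not stated. After ZNF414, the largest falls were ISOC1 (-1.62, SE 0.08), the dynein chain DYNC1I1 (-1.60, SE 0.23), the glutamate transporter SLC1A2 (-1.57, SE 0.17), ROPN1L (-1.43), IDH2 (-1.36, SE 0.06), NCEH1 (-1.31, SE 0.08) and TMEM158 (-1.28, SE 0.13). DYNC1I1 was at -2.31 without siZNF414 replicate 2. IDH2 went from 129 ± 1.29 to 49.9 ± 0.259 CPM.

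Genes of DNA replication fell together at 24 h in Hs700T. Of the G1/S and DNA replication list, 34 of 41 genes were lower, 1 higher and 6 not past the test (adjusted over the list alone, also 34 and 1), with a median log2 fold of -0.58 (camera adjusted p = 1.36e-36, and adjusted p = 0.204 with an estimated correlation). The replicative helicase subunits MCM5 and MCM2 fell by 0.79 and 0.74 on the log2 scale (SE 0.06 each), and PCNA, the sliding clamp of DNA polymerase, fell by 0.70 (SE 0.06). Of the mitosis and G2/M list, 30 of 40 were lower, 1 higher and 9 not past (adjusted over the list alone, 33 and 1). The median of the list was -0.31 (adjusted p = 5.09e-13, and adjusted p = 0.616 with an estimated correlation). The cyclin-dependent kinase CDK1 fell by 0.60 (SE 0.08) and BIRC5 (survivin) by 0.53 (SE 0.07), while CENPF rose (0.47, SE 0.06). Of the MYC targets and ribosome biogenesis list, 21 of 33 were lower, 0 higher and 12 not past (adjusted over the list alone, 27 and 0), including the spermidine synthase SRM (-0.76, SE 0.07) and the RNA polymerase I subunit POLR1B (-0.61, SE 0.07). For this list the median was -0.28 (adjusted p = 2.10e-12, and adjusted p = 0.616 with an estimated correlation). Cytosolic heat shock genes had 9 of 17 lower, 2 higher and 6 not past (adjusted over the list alone, 11 and 2), including the co-chaperone STIP1 (-0.83, SE 0.06) and the chaperonin HSPD1 (-0.61, SE 0.06), which works in mitochondria. Their median log2 fold was -0.30 (adjusted p = 5.24e-06, and adjusted p = 0.616 with an estimated correlation).

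Pancreatic duct and carcinoma markers were higher in Hs700T at 24 h: 9 of 17 rose, 0 fell and 8 did not pass (adjusted over the list alone, 9 and 0). The median of the list was 0.29 (adjusted p = 5.94e-06, and adjusted p = 0.204 with an estimated correlation). The mucin MUC16 rose from 20.4 ± 1.3 to 57.3 ± 0.795 CPM (1.49, SE 0.10), and the keratins KRT17 (1.31, SE 0.12) and KRT19 (0.94, SE 0.13) and the transcription factor SOX9 (0.51, SE 0.09) rose as well. Of the epithelial state list, 13 of 24 were higher, 0 lower and 11 not past (adjusted over the list alone, 13 and 1), including CDH1 (0.69, SE 0.06) and ELF3 (0.69, SE 0.08). The list had a median of 0.18 (adjusted p = 9.82e-04, and adjusted p = 0.623 with an estimated correlation). Of the actin cytoskeleton and focal adhesion list, 20 of 54 were higher, 5 lower and 29 not past (adjusted over the list alone, 23 and 5). Its median log2 fold was 0.14 (adjusted p = 3.20e-04, and adjusted p = 0.713 with an estimated correlation). Its integrins ITGA6 (1.29, SE 0.06) and ITGB4 (0.78, SE 0.07) rose and the membrane linker MSN (moesin) fell (-0.62, SE 0.05). Of the TGF-beta targets, 7 of 24 were higher, 1 lower and 16 not past (adjusted over the list alone, 9 and 3), including TGFBR1 (0.97, SE 0.09) and the cell cycle inhibitor CDKN2B (0.77, SE 0.06). The median of the list was 0.11 (adjusted p = 0.0378, and adjusted p = 0.717 with an estimated correlation). Without siLuc replicate 2 the calls of the epithelial (median 0.17), actin (0.09) and TGF-beta (0.04) lists were lost, the last also without siZNF414 replicate 1 (0.002). Without siLuc replicate 1 the actin median was 0.21.

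Of the cholesterol synthesis and uptake list at 24 h in Hs700T, 14 of 25 were higher, 2 lower and 9 not past (adjusted over the list alone, 14 and 2). For this list the median was 0.22 (adjusted p = 0.00496, and adjusted p = 0.616 with an estimated correlation). HMGCS1 (0.48, SE 0.09) and IDI1 (0.44, SE 0.08), enzymes of the mevalonate pathway, rose, as did INSIG1, which restrains it (0.77, SE 0.13), and DHCR24, a sterol reductase of late cholesterol synthesis, fell (-0.77, SE 0.08). The mitochondrially encoded transcripts had 11 of 13 higher, 0 lower and 2 not past (adjusted over the list alone, 12 and 0), including MT-ND5 (0.39, SE 0.07). Its median log2 fold was 0.30 (adjusted p = 1.60e-04, and adjusted p = 0.634 with an estimated correlation). That median was 0.22 and 0.38 without siLuc replicates 1 and 2, and 0.34 and 0.21 without siZNF414 replicates 1 and 2. In the MCF-7 24 h fit of 4 libraries it was -0.21, with 1 of 13 lower, 0 higher and 12 not past. Camera passed the list there as lower (adjusted p = 0.0273, and adjusted p = 0.855 with an estimated correlation). Of the immediate early and SRF targets, 8 of 28 were higher, 1 lower and 19 not past (adjusted over the list alone, 9 and 1), including KLF2 (1.14, SE 0.16) and KLF6 (0.64, SE 0.07). The median of the list was 0.25 (adjusted p = 0.00484, and adjusted p = 0.717 with an estimated correlation). Of the p53 targets, 6 of 24 were higher, 2 lower and 16 not past (adjusted over the list alone, 6 and 2), including TP53INP1 (1.42, SE 0.20), RRM2B (1.36, SE 0.12) and MDM2 (0.63, SE 0.07). The list had a median of 0.03 (adjusted p = 0.0314, and adjusted p = 0.506 with an estimated correlation). Without siLuc replicate 2 the calls of the cholesterol (median 0.20) and p53 (0.03) lists were lost. The p53 median was 0.10 without siLuc replicate 1 and 0.11 without siZNF414 replicate 2. The other 20 lists had camera adjusted p from 0.0501 to 0.958, and fry passed 9 lists.

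In Hs700T at 24 h, 4475 of 21521 genes passed edgeR's test, 2238 higher and 2237 lower. The count was 2656 without siLuc replicate 1 and 2794 without siZNF414 replicate 2. It was 1339 against a fold of 1.2 and 270 with all 16 libraries in the fit, where TMEM158 was the only one of the 16 genes of largest change no longer past the threshold. Of the 31 list examples above, MCM5, MCM2, RRM2B, TP53INP1, STIP1, HSPD1, ITGA6, TGFBR1 and KRT17 were still past it there. The authors' deposited table held 1162 genes at an adjusted p under 0.05, 598 higher and 564 lower, and 1134 of these also passed here in the same direction.

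**Figure D2:**
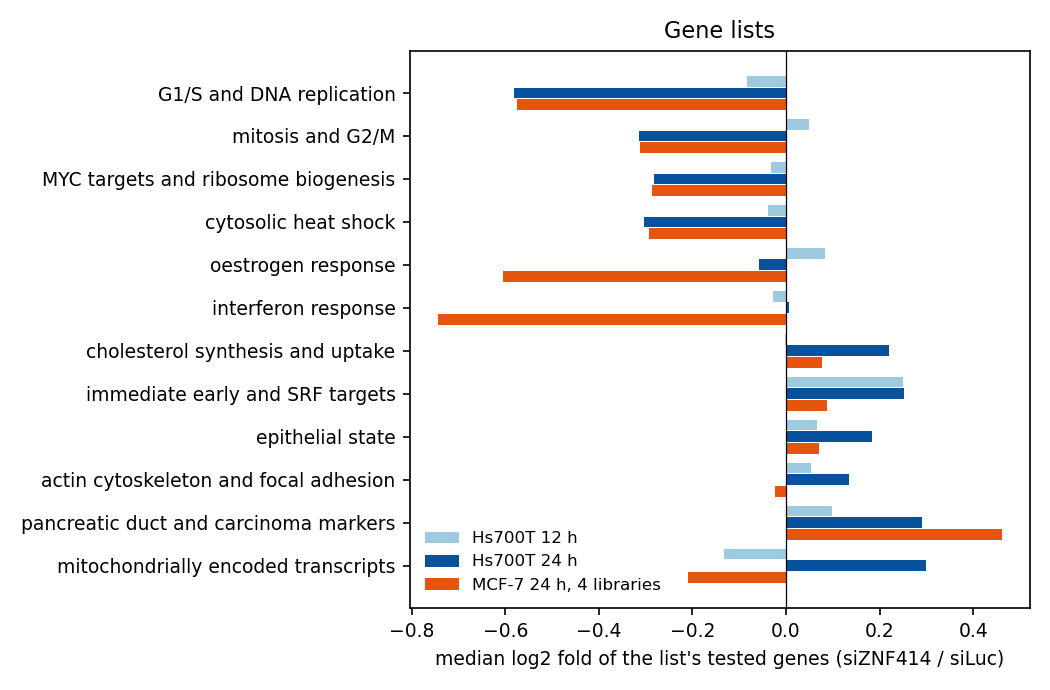
Median log2 fold change (siZNF414 over siLuc) of the tested genes of 12 gene lists in Hs700T at 12 h, Hs700T at 24 h and MCF-7 at 24 h, the last from a fit of its 4 libraries. The G1/S and DNA replication list lies at -0.08, -0.58 and -0.57.

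Whether the siRNA effect in Hs700T differed between 24 h and 12 h was tested as an interaction. The effect on MUC16 was larger at 24 h by 1.499 on the log2 scale (SE 0.14, adjusted p = 2.33e-04), the effects on C15orf52 by 1.35 (SE 0.12, adjusted p = 2.33e-04) and AHNAK2, a scaffold protein gene, by 0.835 (SE 0.08, adjusted p = 2.33e-04), and that on ITGB8 by 1.08 (SE 0.11, adjusted p = 3.49e-04). MUC16 had a log2 fold change of -0.01 at 12 h and 1.49 at 24 h. The test passed 494 genes, with a higher value at 24 h for 203 and a lower one for 291. The count was 243 without siLuc 12 h replicate 1, 155 (91 higher, 64 lower) without siLuc 12 h replicate 2, 42 (21 and 21) without siZNF414 12 h replicate 1, 101 without siZNF414 12 h replicate 2, 146 (80 and 66) without siLuc 24 h replicate 1, 888 (454 and 434) without siLuc 24 h replicate 2 and 139 (77 and 62) without siZNF414 24 h replicate 2. The excess of lower over higher values was lost in the fits with a split given. DESeq2 passed 1035 genes.

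Genes past the threshold at both times in Hs700T were counted to see which changes lasted. Of the 21521 genes tested at both times, 269 were higher at both against 29.8 for independent lists (Fisher's exact test, p = 2.83e-244) and 111 lower at both against 12.5 (p = 2.50e-98), with none in opposite directions. The 10 with the smallest larger adjusted p were UBE2V2, LBR, PDCD4, ITGB8, STC1, ITGA6, PLEKHA1, RCN2, TMX1 and KIF5B, and all 10 were higher. RCN2, a calcium-binding protein of the secretory pathway, had log2 fold changes of 0.79 and 0.93 (SE 0.06 each), and KIF5B, a kinesin heavy chain, of 0.77 and 0.81 (SE 0.06 each). Across genes, which are not independent replicates, the log2 fold changes of the 2 times had a Pearson r of 0.188 over the 21521 genes tested by edgeR and 0.395 over 17327 genes by DESeq2. Of the genes called at 12 h, 98.3% had the same sign at 24 h.

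The contrast in MCF-7 at 12 h asked the same question in breast cancer cells. No gene passed edgeR's test: 0 of 22806, with 2151 at an unadjusted p under 0.05, and DESeq2 called 101. The 5 genes with the smallest p were PDCD4, from 22.7 ± 1.24 to 66.8 ± 1.09 CPM (n = 2 per group; log2 fold change 1.56, SE 0.15, adjusted p = 0.259), UBE2V2 (2.26, SE 0.26, adjusted p = 0.351), TMX1 (1.68, SE 0.20, adjusted p = 0.351), CCNG2, an unconventional cyclin (1.24, SE 0.16), and the RNA helicase DDX1 (1.06, SE 0.15). The cytosolic ribosomal proteins had a median log2 fold of 0.85 with all 70 genes not past the test (adjusted over the list alone, 0; camera adjusted p = 2.09e-20, and adjusted p = 0.657 with an estimated correlation), and the nuclear-encoded mitochondrial respiratory chain one of 0.77 with all 49 not past (adjusted over the list alone, 0; adjusted p = 3.21e-14, and adjusted p = 0.657 with an estimated correlation). Cholesterol synthesis and uptake genes (median 0.27, 24 genes, adjusted p = 0.0162), NRF2 targets (median 0.31, 21 genes, adjusted p = 0.0275) and genes around ZNF414 (median 0.57, 8 genes, adjusted p = 0.0275) also passed camera, each with no member past the test and 0 adjusted over the list alone, and each with adjusted p = 0.657 with an estimated correlation. The NRF2 call was lost without siLuc replicate 1 (median 0.30) or siZNF414 replicate 2 (0.08), that of genes around ZNF414 without siZNF414 replicate 2 (0.07) and that of cholesterol genes without siLuc replicate 2 (0.22). The cholesterol median was 0.10 without siZNF414 replicate 2. Without siZNF414 replicate 1 the medians were 0.40 for cholesterol genes, 0.49 for NRF2 targets, 0.95 for genes around ZNF414, 1.31 for ribosomal proteins and 1.19 for the respiratory chain. The other 28 lists had adjusted p from 0.0803 to 0.747, and fry passed 0.

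Replicate 2 of the MCF-7 siZNF414 12 h group stood apart from the other 7 MCF-7 libraries. Its correlation with them across genes was 0.864 to 0.886, and each of the others had a partner at 0.986 or more. Its log2 ratio to replicate 1 ran from a median of 1.08 in the decile of shortest transcripts to -0.99 in the decile of longest. The size of the shift in the lists of short ribosomal protein and respiratory chain transcripts moved with it: without this library their medians were 0.10 and 0.07. These medians remained positive, and both lists kept their camera calls. Leaving it out gave 59 genes past edgeR's test, 52 higher and 7 lower, and leaving out replicate 1 instead gave 10310. The authors' deposited table held 431 genes at an adjusted p under 0.05, 239 higher and 192 lower.

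**Figure D3:**
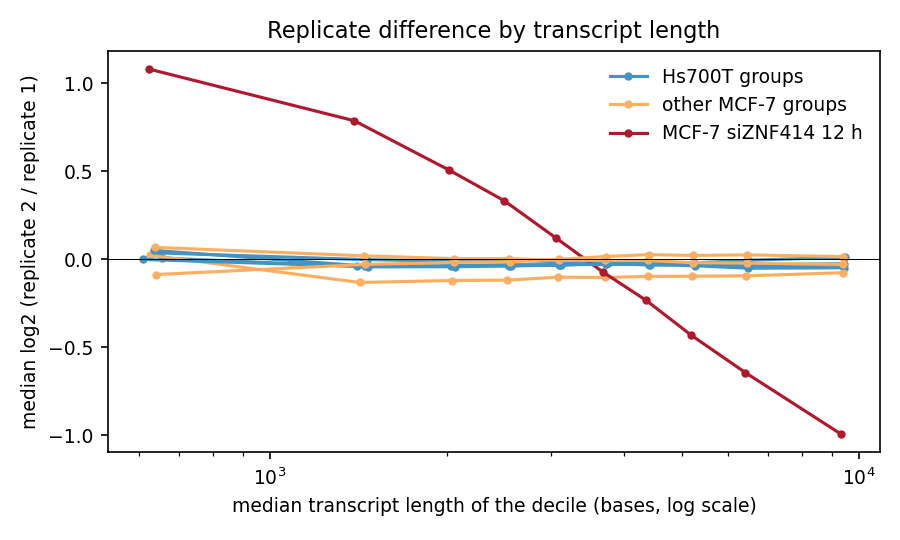
Median log2 ratio of replicate 2 to replicate 1 in each group, by decile of transcript length (bases, log scale). MCF-7 siZNF414 at 12 h runs from 1.08 to -0.99.

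The contrast in MCF-7 at 24 h asked which changes were present at the later time in this line. PDCD4 rose from 19.2 ± 0.770 to 85.8 ± 2.08 CPM (n = 2 per group; log2 fold change 2.16, SE 0.16, adjusted p = 0.0287) and CCNG2 from 11.5 ± 0.117 to 46.2 ± 2.71 CPM (2.01, SE 0.17, adjusted p = 0.0403). They were the 2 of 22806 genes that passed edgeR's test, with 2062 at an unadjusted p under 0.05 and 379 called by DESeq2. No gene passed when any single 24 h library was left out: 0 without siLuc replicate 1, siLuc replicate 2, siZNF414 replicate 1 or siZNF414 replicate 2. The log2 fold changes stayed at 2.12 to 2.21 for PDCD4 and 1.95 to 2.07 for CCNG2 in these fits. The fit of 8 libraries shares its spread with the 12 h libraries. With the 4 libraries of 24 h alone, 4002 genes passed, 1931 higher and 2071 lower, and with only the 12 h library that stood apart left out, an alternative added after its values were seen, 2921 passed, 1441 higher and 1480 lower. The authors' deposited table held 1765 genes at an adjusted p under 0.05, 816 higher and 949 lower, of which 1648 passed in the fit of 4 libraries in the same direction.

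By that fit of 4 libraries, to which the rule for named genes was applied after its values were seen, STC1 rose from 5.41 ± 1.01 to 26.9 ± 0.707 CPM (2.33, SE 0.14), UBE2V2 from 16.3 ± 0.219 to 75.0 ± 1.10 CPM (2.21, SE 0.08) and PKP1, a desmosomal plakophilin, from 9.27 ± 0.855 to 35.5 ± 1.90 CPM (1.94, SE 0.11). SMN1 (1.70, SE 0.15) is uncertain because SMN2 is a near-identical copy, and SH3BGRL2 (1.64, SE 0.12) and CTGF, a secreted matricellular protein (1.58, SE 0.40), followed. CTGF stood at 60.7 and 20.1 CPM in the siZNF414 libraries against 13.3 and 13.7 CPM in the siLuc libraries, and its log2 fold change in the fit of 8 libraries was 0.57 without siZNF414 replicate 1 and 2.17 without replicate 2. SAMD9 stood at 488 and 228 CPM in the siLuc libraries, and its log2 fold change in that fit was -1.06 without siLuc replicate 1. The largest falls were the adenosine receptor ADORA1 (-2.07, SE 0.18), the proteoglycan SPOCK1 (-2.03, SE 0.12), GPX8 (-1.96, SE 0.15), the sulfate transporter SLC26A2 (-1.92, SE 0.11), the transglutaminase TGM2 (-1.92, SE 0.11), ZNF414, the kinase TNIK (-1.72, SE 0.15) and SAMD9 (-1.72, SE 0.30). TGM2 went from 258 ± 40.8 to 68.2 ± 3.08 CPM.

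Genes of the oestrogen response were lower in MCF-7 at 24 h. List medians and camera's adjusted p in this paragraph are from the fit of 8 libraries. Of 31 listed genes tested, 0 passed in the fit of 8 libraries (adjusted over the list alone, 16 lower and 1 higher), and in the fit of 4 libraries 24 were lower, 1 higher and 6 not past (adjusted over the list alone, 25 and 2). For this list the median was -0.61 (camera adjusted p = 3.63e-17, and adjusted p = 0.438 with an estimated correlation), and its examples were PDZK1, a scaffold protein (-1.62, SE 0.11), PGR, the progesterone receptor (-1.53, SE 0.11), MYBL1 (-1.23, SE 0.08) and the protease PRSS23 (-0.98, SE 0.07). Of the G1/S and DNA replication list, 0 of 41 passed in the fit of 8 libraries (adjusted over the list alone, 25 lower), and in the fit of 4 libraries 35 were lower, 0 higher and 6 not past (adjusted over the list alone, 35 and 2; median -0.58 in the fit of 8, adjusted p = 2.24e-19, and adjusted p = 0.587 with an estimated correlation). MCM2 (-0.88, SE 0.08), MCM5 (-0.86, SE 0.08) and CDC45 (-0.79, SE 0.08), all parts of the replicative helicase, fell in the fit of 4. Of the mitosis and G2/M list, 21 of 40 were lower in that fit, 1 higher and 18 not past (adjusted over the list alone, 27 and 1), and 0 passed in the fit of 8 (adjusted over the list alone, 0). Its median log2 fold was -0.31 (adjusted p = 9.02e-06, and adjusted p = 0.730 with an estimated correlation). The mitotic transcription factor FOXM1 fell (-0.62, SE 0.07) and CENPF rose (0.80, SE 0.08).

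List medians and camera's adjusted p in this paragraph are from the fit of 8 libraries unless stated. Interferon response genes in MCF-7 at 24 h had a median of -0.75 (camera adjusted p = 2.88e-13, and adjusted p = 0.730 with an estimated correlation), with 0 past the test (adjusted over the list alone, 0). In the fit of 4 libraries 12 of 38 were lower, 0 higher and 26 not past (adjusted over the list alone, 22 and 0). The median there was -0.74 (camera adjusted p = 1.07e-07, and adjusted p = 0.855 with an estimated correlation). USP18, a brake on interferon signalling (-1.13, SE 0.26), and OAS3, a sensor of double-stranded RNA (-0.78, SE 0.20), were among them. Much of the fall rested on siLuc replicate 1, where USP18 stood at 113 CPM against 56.5 CPM in replicate 2 and OAS3 at 1380 against 836 CPM. In the fit of 8 libraries the list's median was -0.20 without siLuc replicate 1 and -1.14 without siLuc replicate 2, and without replicate 1 the log2 fold changes of USP18 and OAS3 were -0.54 and -0.38. The MYC targets and ribosome biogenesis list had 16 of 33 lower and 0 higher in the fit of 4 (adjusted over the list alone, 25 and 0) and 0 past in the fit of 8 (adjusted over the list alone, 0). The median of the list was -0.29 (adjusted p = 1.72e-04, and adjusted p = 0.587 with an estimated correlation). Cytosolic heat shock genes had 9 of 17 lower and 0 higher in the fit of 4 (adjusted over the list alone, 9 and 0) and 0 past in the fit of 8 (adjusted over the list alone, 0). The list had a median of -0.29 (adjusted p = 0.00336, and adjusted p = 0.749 with an estimated correlation). Pancreatic duct and carcinoma markers had 6 of 17 higher and 1 lower in the fit of 4 (adjusted over the list alone, 9 and 1) and 0 past in the fit of 8 (adjusted over the list alone, 0), including S100P (0.56, SE 0.08) and CEACAM6 (0.58, SE 0.10). Its median log2 fold was 0.46 (adjusted p = 0.0348, and adjusted p = 0.587 with an estimated correlation). The pancreatic acinar and endocrine list passed with 5 genes tested (adjusted p = 0.0378, and adjusted p = 0.587 with an estimated correlation) and 0 genes past (adjusted over the list alone, 1), and did not pass with the 4 libraries alone or without any single library (medians 0.51 and 0.23 without siLuc replicates 1 and 2, 0.02 and 0.56 without siZNF414 replicates 1 and 2). The duct list's call was lost without siLuc replicate 2 (median 0.26). The other 25 lists had adjusted p from 0.0503 to 0.964, and fry passed 0 lists.

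The effects at 24 h and 12 h in MCF-7 were compared by the same interaction. edgeR passed 0 of 22806 genes, with 1028 at an unadjusted p under 0.05 and 0 by DESeq2. PDCD4 had log2 fold changes of 1.56 at 12 h and 2.16 at 24 h. Without replicate 1 of the siZNF414 12 h group, which leaves the library that stood apart as the only one of its group, the count was 8463.

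Whether the siRNA acted differently in the 2 lines was tested in a fit of all 16 libraries. At 12 h edgeR passed 0 of 24533 genes, with 1638 at an unadjusted p under 0.05 and 1 by DESeq2, and the count was 8729 without replicate 1 and 9 without replicate 2 of the MCF-7 siZNF414 12 h group. At 24 h it passed 0, with 1439 at an unadjusted p under 0.05 and 164 by DESeq2, and 1 or 2 passed without siLuc replicate 1 or 2 of MCF-7. The smallest adjusted p at 24 h was 0.0803, for genes that included GPX8, with log2 fold changes of -1.97 in MCF-7 and -0.36 in Hs700T, and the potassium channel KCNK6, with -0.36 and 1.12. Without the MCF-7 12 h library that stood apart, 593 genes passed at 24 h, 227 with a higher value in MCF-7 and 366 with a lower one.

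Calls shared by the lines were counted to see which changes did not depend on the line. At 24 h, PDCD4 and CCNG2 were higher in both (2 genes against 0.216 for independent lists; Fisher's exact test, p = 0.0117), and the log2 fold changes of the lines had a Pearson r of 0.311 across 20073 genes. With MCF-7 calls from the fit without the library that stood apart, 656 genes were higher in both lines at 24 h against 149 for independent lists (Fisher's exact test, p = 1.04e-291), 820 were lower in both against 151, and 60 went in opposite directions. By DESeq2, 202 genes were called in the same direction. At 12 h, 0 genes were shared, 55 without that library and 38 by DESeq2. UBE2V2, STC1, ITGB8, ITGA6, PLEKHA1, LBR, RCN2, TMX1 and KIF5B, higher at both times in Hs700T, were also past the threshold in the fit of the 4 MCF-7 libraries of 24 h, with log2 fold changes from 1.07 (ITGA6) to 2.33 (STC1). Of the 15 genes named as largest rises that had a 3' UTR sequence, 14 carried GTCTTAA there, PDCD4, CCNG2, UBE2V2, ITGB8 and STC1 among them, and 7 of 18 named as largest falls carried GCTCTTC. In the other direction, 4 of the 15 rises carried GCTCTTC and 0 of the 18 falls carried GTCTTAA. The 18 falls include ZNF414 itself, which carried neither. Both 7-mers were picked because they led in these same fold changes. Of the genes not called in Hs700T at 12 h, 11.8% carried GTCTTAA and 12.8% carried GCTCTTC.

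**Figure D4:**
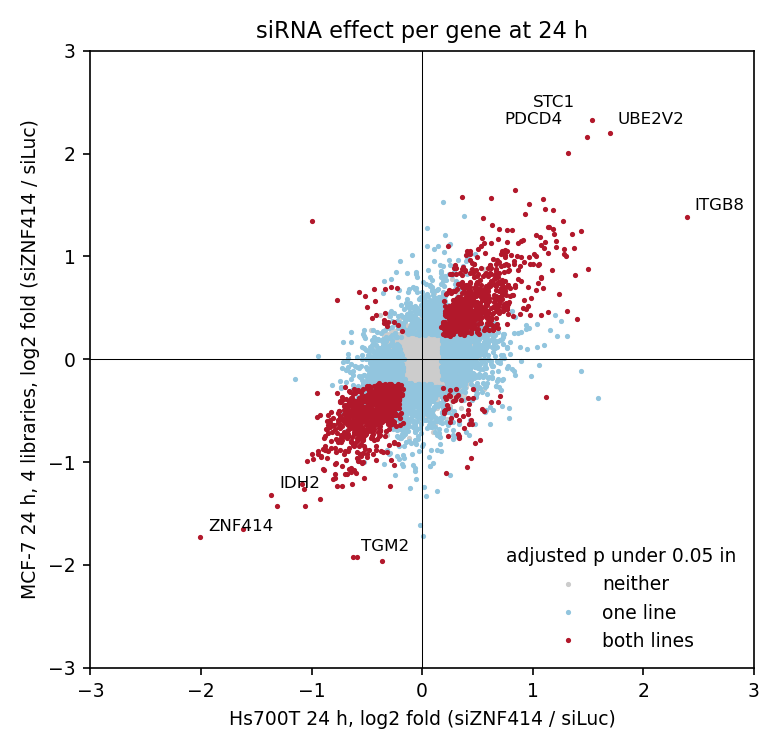
Log2 fold change (siZNF414 over siLuc) at 24 h in Hs700T and in MCF-7, the latter from a fit of its 4 libraries, with 1 point for each of 11007 genes tested in both with a mean over 5 CPM in each line. Colour marks genes with an adjusted p under 0.05 in neither, one or both lines; STC1, PDCD4, UBE2V2 and ITGB8 lie at upper right and ZNF414, IDH2 and TGM2 at lower left.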

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

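In this part, the fit without the MCF-7 library was added after its values were seen, and the other tests were planned. The results below were marked because an effect of the siRNA differed between times or between lines in an interaction test, not because 2 separate counts differed.

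In Hs700T the effect differed between 24 h and 12 h for 494 genes. Values are log2 fold changes at 24 h minus those at 12 h. Only genes that the report already names were drawn from these, so they need not represent all 494. Among genes whose effect was more positive at 24 h, the difference was 1.499 for MUC16, 1.348 for C15orf52, 1.268 for IGFL2-AS1, 1.075 for ITGB8, 0.9127 for KRT17, 0.835 for AHNAK2, 0.6911 for LIPA, 0.57 for CDKN2B, 0.5459 for ITGB4, 0.471 for MT-ND5, 0.41 for STC1 and 0.376 for CDH1. Duct, adhesion and epithelial genes are among them, and members of those lists were a source of the named genes. Among genes whose effect was more negative at 24 h, it was -1.166 for SLC1A2, -1.05 for ROPN1L, -0.872 for PTGS2, -0.736 for ISOC1, -0.654 for IDH2, -0.5156 for ACLY, -0.4458 for LAMB1 and -0.4382 for MSN. Replication and mitosis genes had differences of -0.709 for CDK1, -0.6949 for BIRC5, -0.6074 for MCM5, -0.558 for PCNA and -0.5494 for MCM2. The chaperone genes STIP1 and HSPD1 had -0.6372 and -0.5562, and the spermidine synthase gene SRM had -0.5405. IGFL2-AS1 is an antisense gene and remains uncertain.

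Between the lines at 24 h, 593 genes differed in the fit lacking MCF-7 siZNF414 12 h replicate 2, against 0 in the fit of all 16 libraries. AXIN2, a target of Wnt signalling, had log2 fold changes of 1.45 in the MCF-7 fit lacking that library and -0.39 in the Hs700T fit. Its difference, MCF-7 minus Hs700T, was 1.84 (SE 0.12) in the fit of both lines lacking that library. Over all genes tested there, 593 of 25610 differed, so a 0 in a short list does not show that the lines were alike. The lists were counted and not tested as sets for this difference. Of the oestrogen response genes 11 of 32 differed, all 11 lower in MCF-7, and of the G1/S and mitosis lists 0 of 41 and 0 of 40 differed.

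More genes were called at 24 h (4475) than at 12 h (407) in Hs700T, and the libraries also differed in depth. Deeper sequencing at 24 h is a technical candidate explanation. With all 8 Hs700T libraries thinned to 37.3 M counts, 4188 and 410 genes were called, a ratio of 10.2 (10.215), against 10.995 at full depth. This argues against depth. A longer time for secondary changes may also have added calls, and no biological explanation was tested.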

How the results depend on the processing

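The fits lacking MCF-7 siZNF414 12 h replicate 2, the lists in fits of 4 libraries, the crossed block and the naming rule on the MCF-7 24 h fit of 4 libraries were chosen after results were seen. Among the 130 gene list and 376 named gene results, no call was made in the opposite direction under an alternative. In Hs700T at 12 h, list medians changed sign where the call was lost, from 0.09 to -0.01 for TGF-beta and from 0.05 to -0.01 for apoptosis genes without siLuc replicate 2, and from 0.05 to -0.01 for mitosis genes without siLuc replicate 1. Of 1202 values for 130 gene list results, called or not, 1045 kept their status, 91 lost a call and 66 gained one. Of 4733 values for 376 named gene results, 3884 kept their status, 402 lost a call and 447 gained one. A kept status includes results that were not called at first and stayed so, as in 245 of 299 named gene values in MCF-7 at 12 h. In Hs700T at 12 h (407 genes), the count was 618 without a filter on low counts, 950 with a replicate block, 10 with all 16 libraries, 93 against a fold of 1.2 and 167 to 298 with 1 library left out. In Hs700T at 24 h (4475), it was 270 with all 16 libraries, 1339 against a fold of 1.2 and 2656 to 4234 with 1 library left out. In MCF-7 at 12 h (0), it was 101 by DESeq2, 333 without a filter, 41 with all 16 libraries and 0 to 10310 with 1 library left out. In MCF-7 at 24 h (2), it was 379 by DESeq2, 171 without a filter, 0 with a replicate block, 0 with the block crossed, 4002 with its 4 libraries, 706 with all 16, 2921 lacking the 12 h library and 0 with any 24 h library left out. The common biological coefficient of variation was 0.0762 in Hs700T, 0.259 in MCF-7, 0.135 without that library and 0.0978 in the MCF-7 24 h libraries alone, and the fit of 8 MCF-7 libraries includes the spread of that library. Pairing by replicate number had correlations of 0.20, 0.44, 0.26 and -0.14 in the 4 comparisons in the order above, and the labels do not say that equal numbers share a batch. In Hs700T at 24 h the count rose to 6437 with a replicate block and to 4940 without a filter on low counts. The time difference in Hs700T (494) was 1035 by DESeq2, 1228 without a filter, 2179 with a block and 42 to 888 with 1 library left out, and in MCF-7 (0) it was 0 to 8463. The line difference at 12 h (0) was 1 by DESeq2, 132 without a filter and 0 to 8729 with 1 library left out. At 24 h (0) it was 164 by DESeq2, 64 without a filter, 16 with the stricter filter, 593 lacking the library and 0 to 2 with 1 of the 24 h libraries left out.

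ZNF414 in Hs700T at 12 h was -1.67 and not past the threshold with all 16 libraries. In MCF-7 at 12 h it was -1.39 and past it without a filter, and -1.93 to -0.85 with 1 library left out. In MCF-7 at 24 h it was past it by DESeq2 (-1.74), without a filter (-1.74), with 4 libraries (-1.73), with all 16 (-1.74) and lacking the library (-1.72). The lists past the threshold in Hs700T at 12 h (9) became 0 with an estimated correlation, 0 by fry and 5 to 15 with 1 library left out. At 24 h (12) they became 0 with an estimated correlation. In MCF-7 at 12 h (5) they became 0 with an estimated correlation, 0 by fry, 8 with a block and 8 to 11 with 1 library left out, and at 24 h (8) 0 with an estimated correlation and 0 by fry. Genes called in the same direction in both lines at 24 h (2) were 202 by DESeq2 and 1476 lacking the library. They were 38 and 55 in place of 0 for both lines at 12 h, 32 and 58 in place of 0 for both times in MCF-7, 103 and 295 in place of 2 for Hs700T at 12 h and MCF-7 at 24 h, and 42 and 57 in place of 0 for Hs700T at 24 h and MCF-7 at 12 h. The authors' calls in MCF-7 at 12 h (431) were 1285 at an adjusted p under 0.1. Why these counts moved was not tested, except that fitting fewer or more libraries changes the spread that the test uses.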

Other observations

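In this part, the tests for the loss of long transcripts and for RNA of Hs700T cells were written after results were seen, and so were the fits lacking the MCF-7 12 h library and those of 4 libraries. Several genes moved the same way in both lines at 24 h. ACLY, which makes cytosolic acetyl-CoA, had a log2 fold change of -0.996 in Hs700T and -0.92 in the fit of the 4 MCF-7 libraries. The laminin chain gene LAMB1 had -0.90 and -0.87, and DHCR24 -0.77 and -0.72. INSIG1 had 0.77 and 1.06, IDI1 0.44 and 0.61, TGFBR1 0.97 and 1.51, RRM2B 1.36 and 1.22, and TP53INP1 1.42 and 1.27. The p53 targets did not rise as a list in the 4 MCF-7 libraries. There 12 of 25 were lower, 4 higher and 9 not past, with a median of -0.26 (camera adjusted p = 0.234). AGO2, the slicing protein of RNA interference, had -0.66 and -0.31. No difference between lines was detected at 24 h for RNA interference genes (0 of 13) or cholesterol genes (0 of 26), but this does not show that the lines were alike. With all 16 libraries 0 of 24533 genes passed, so no list could have any. A 0 in a list this short also says little in the fit lacking the MCF-7 12 h library, where a small share of all genes passed. In the latter fit 4 of 25 p53 targets and 3 of 24 TGF-beta targets differed. PTGS2, which encodes an inducible cyclooxygenase, had -1.20 in Hs700T at 24 h.

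In MCF-7 at 12 h without siZNF414 replicate 2, 11 lists passed camera at the preset correlation and 0 with an estimated one. Among them were mesenchymal state genes, with a median of 0.57, 0 of 13 members past the test and 5 higher adjusted over the list alone (adjusted p = 0.665 with an estimated correlation). Oestrogen response genes had a median of -0.16, 0 of 32 members past and 1 lower adjusted over the list alone (adjusted p = 0.775 with an estimated correlation). The fit without siZNF414 replicate 2 left a lone siZNF414 library at 12 h. Fibroblast markers, also higher there, had a median of 0.30. Some of them lay near 0 in MCF-7 at 12 h: THY1 averaged 0.00536 CPM with siLuc and 0.150 CPM with siZNF414 over all libraries. COL1A1 averaged 13.6 and 15.4 CPM. List medians, means and tests differed in sign in Hs700T for interferon and RNA interference genes at 24 h and for ER chaperone, cholesterol, fatty acid, YAP/TEAD, matrix and luminal genes at 12 h. They did so in MCF-7 for mitosis, actin and TGF-beta genes at 12 h and for NF-kB, matrix, mesenchymal, RNA interference and luminal genes at 24 h, and none of these lists passed the test there.

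Some of the genes that moved with the siRNA shared short 3' UTR sites in both lines, GTCTTAA in 14 of the 15 named largest rises (PDCD4 and CCNG2 included) and GCTCTTC in 7 of the 18 named largest falls, and seed pairing of the siRNAs themselves is a candidate explanation. GTCTTAA lay in 0 of the 18 falls, but GCTCTTC also lay in 4 of the 15 rises, so among named genes it separated falls from rises less clearly. GTCTTAA led all 7-mers among higher genes in 4 of 4 comparisons, with a smallest distance of 8.36 SD from 7-mers of the same composition. GCTCTTC led among lower genes in 3 of 4, with a smallest distance of -6.06 SD over those 3. In MCF-7 at 12 h it came second to CTTCTCC, at -3.79 SD, inside the bound of 5 SD set beforehand. Both 7-mers were picked because they led in these same fold changes, so their shares among called genes are no separate test. These shares were not adjusted for UTR length. GTCTTAA lay in the 3' UTR of 217 of 252 genes higher in Hs700T at 12 h, against 11.8% of 10226 genes not called. GCTCTTC lay in 65 of 106 lower genes there, against 12.8%. At 24 h most called genes lacked them, but the shares still exceeded those of genes not called. GTCTTAA lay in 468 of 1522 higher genes in Hs700T (30.7% against 11.3%) and 422 of 1352 in the 4 MCF-7 libraries (31.2% against 11.3%). GCTCTTC lay in 401 of 1902 lower genes in Hs700T (21.1% against 11.7%) and 321 of 1552 in the 4 MCF-7 libraries (20.7% against 11.7%). Both sites fit relief from repression by the control siRNA and repression by the ZNF414 siRNA, but the siRNA sequences were not analysed here. The effect of losing ZNF414 itself was not tested and remains open. GCTCTTC sites in the 3' UTRs of the replication genes themselves were argued against as the cause of their fall. The 39 of 41 G1/S genes without GCTCTTC still had medians of -0.581 in Hs700T and -0.573 in MCF-7 (fit of 8 libraries) at 24 h. Overlapping sites in these genes, such as CTCTTCA, and sites outside the 3' UTR were not looked for, so they remain open.

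MCF-7 siZNF414 12 h replicate 2 stood apart, and loss of long transcripts is a technical candidate explanation. Its difference from replicate 1 fell with transcript length (Spearman rho -0.655 across genes, other 7 pairs -0.172 to 0.141), which fits but covers only part, since the SD of the difference went from 0.874 to 0.678 after the length trend. Shallower sequencing gave 6.00% of the observed SD and is argued against. RNA of Hs700T cells, at 0.722 times the ratio in other MCF-7 libraries, is argued against too. Calls in MCF-7 at 12 h may therefore rest on this library (10310 without replicate 1 and 59 without replicate 2), and no biological explanation was tested.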
